A study of Mus musculus with 6 samples.

How the data were processed

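RNA was sequenced from 6 samples of mouse primary macrophages, 3 pretreated with vehicle and 3 with rmMETRNL, each then challenged with Candida albicans for 6 h. Per the labels' protocols, the libraries were made with an Illumina TruSeq RNA kit from 1 ug of total RNA. The same text describes taking retinas, which conflicts with the macrophages named in the other labels, so a list of retina markers was checked. The authors deposited 1 table of FPKM values with a row for each of 54532 genes and a column for each library, together with each gene's name, position, length and biotype. The submitters' processing notes name GRCm38 and mm10. The aligner, the counting tool, their versions, the annotation release and whether counting used the strand are not given in the sources used here. Gene coordinates in the table were identical in start and end to GENCODE M21 (GRCm38) for 53499 of the 54409 genes matched by identifier (98.3%), and coordinates are given as in the table. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart. Counting overlaps on either strand, 12 of 206 genes checked shared over 10% of their exon bases with another gene.

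The columns carry short names that the labels do not spell out. The letters of their names set 3 columns apart that share the first letter of rmMETRNL, and these were taken as the rmMETRNL samples and the other 3 as vehicle. The split into groups is sure and its direction rests on this reading. The number in each name was taken as the replicate number of the labels.

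FPKM means fragments per kilobase of gene, scaled to a common library size, and the deposited values were scaled by the authors with the gene lengths in the same table. Each value times its gene length was a whole multiple of 1 step per library for 100% of values, within a tolerance of 0.05 reads, so the reads (or read pairs) behind each value were recovered. They sum to between 13235001 and 18145733 per library. At a length of 1 kb, 10 reads correspond to 0.549 to 0.748 FPKM, which limits what can be seen of low genes. No interval for counting error was added, as the spread between libraries was used for each test.

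Genes with a mean of at least 1 FPKM over the 6 libraries (9867 genes) were tested with limma 3.58.1 in R 4.3.3, with the mean-variance trend, on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this scale, which understates the change of low genes. Files of whole counts were foreseen as the alternative case in the plan, and as the table holds FPKM the test planned for FPKM was used. Gene lists (42, of which 35 had at least 5 tested members) were tested with camera, which asks whether the genes of a list move differently from the others, with a preset correlation of 0.01, on the same values, adjusted over the lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. For each list the members were also counted at an adjusted p of 0.05 over all genes tested and adjusted over the list alone.

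The lists, the tests, the other settings given next and the rule for naming genes were fixed before the data were examined. Genes named are the 12 with the largest fold change in each direction among those past the threshold whose groups do not overlap, leaving out unnamed, predicted and pseudogene models, or, as happened here, the 10 with the smallest p in each direction, given as values only. Up to 4 members with the smallest p of each list described, Metrnl and Kit, and the 2 most abundant members of each marker list of other cell types are named as well. Clec7a, which the table classes as a polymorphic pseudogene, is named through its list.

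Other settings also fixed then were pseudocounts (0.1 and 0.01), no filter and a minimum of 5 FPKM, rescaling to TPM, median-of-ratios scaling, quantile normalization, limma without the trend or with array weights, the replicate number as a block, other thresholds, and leaving out each library. Alternatives chosen after seeing the data were limma voom on the recovered reads, robust variance estimation, protein-coding genes only, leaving out the genes that share over 10% of their words with another gene, leaving out Gapdh from the lists, and removal of each library's trend with gene length or GC content. The share of 31-base words of a gene that occur in another gene was computed from the longest GENCODE M21 transcript of each gene.

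The fit was tested on simulated data for this comparison, drawn from the real libraries' means, depths and within-group spread, with up to 50 genes changed at each size among 9879. Limma called 26.0% of genes changed 1.25-fold, 54.2% of those changed 1.5-fold, 73.5% of those changed 2-fold and 93.8% of those changed 4-fold, and 0.103% of unchanged genes. Voom called 30.0%, 58.3%, 83.7% and 93.8% of the changed genes and 0.0826% of the unchanged ones. All sizes were simulated together, and the larger changes called eased the adjusted threshold for the smaller ones. In the real libraries, 14 of 5382 genes with a mean of at least 5 FPKM exceeded a log2 fold change of 1. The shares for 1.25-fold and 1.5-fold may therefore be too high for the real data. Camera called a list of 20 genes raised 1.25-fold and called 0 of 40 unchanged lists. With the real libraries regrouped into other sets of 3 and 3, however, camera called 1 to 6 lists. The simulated lists therefore do not show how often unchanged real lists are called. The estimated correlation within a real list reached 0.574 (ribosomal proteins). The largest median rise of a tested list was 1.12-fold (hypoxia and HIF-1 targets), below the simulated one. Pairs of libraries of the same group differed by more than sampling noise (chi-square per degree of freedom 4.05 to 7.77), so no library was counted as a duplicate, and pairs across groups gave 6.73 to 14.3. Sequence features were computed with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.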

Results

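RNA-seq was measured in 6 libraries of primary macrophages from wild-type mice, all taken 6 h after a challenge with the yeast Candida albicans. Before the challenge, 3 samples had received vehicle and 3 had received rmMETRNL for 6 h. The labels name this treatment for METRNL (meteorin-like), a secreted protein that macrophages also make themselves. Both groups met the fungus, so the comparison is between pretreatments and does not give the response to the fungus itself. The labels do not say whether the 3 samples of a group came from separate animals or cultures, and p-values measure the spread between these samples, which may be technical. The column names were read as vehicle and rmMETRNL from their letters, and every direction given here rests on that reading. The FPKM values resolve into whole reads (or read pairs), 15027642, 13235001 and 18145733 in vehicle libraries 1, 2 and 3 and 15427930, 15744878 and 14861916 in rmMETRNL libraries 1, 2 and 3. Between 18723 and 19613 genes had at least 1 read in a library.

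The libraries carried the transcripts of activated macrophages. The ferritin heavy chain gene Fth1 was the most abundant, at 36005 ± 827 FPKM in vehicle libraries (mean ± SD, n = 3, as for all values below) and 30640 ± 1663 FPKM in rmMETRNL libraries. The chemokine gene Ccl3 stood at 9034 ± 519 and 9857 ± 300 FPKM, the secreted phosphoprotein gene Spp1 at 6608 ± 261 and 6295 ± 196 FPKM, and the lysozyme gene Lyz2 at 5460 ± 382 and 5567 ± 139 FPKM. Of 16 macrophage identity genes, 16 were above the level tested, a mean of 1 FPKM.

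The comparison asked which genes differ between macrophages pretreated with rmMETRNL and with vehicle before they meet Candida. The differences were small. Hypoxia and HIF-1 target genes rose as a list in the rmMETRNL libraries, by a median of 0.17 on the log2(FPKM + 1) scale, and so did the lists of inflammatory cytokines (0.12), apoptosis and survival genes (0.09), immediate-early genes (0.09), unfolded protein and integrated stress response genes (0.08), NF-kappaB targets (0.08) and glycolysis genes (0.05). The lists of ribosomal proteins (-0.15) and of the TCA cycle and oxidative phosphorylation (-0.08) fell. These 9 of 35 lists passed camera with a preset correlation of 0.01 at an adjusted p of 0.05, and 0 passed with an estimated correlation (lowest adjusted p = 0.441).

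No single gene passed the test. Limma on log2(FPKM + 1) called 0 of 9867 genes at an adjusted p of 0.05 (lowest adjusted p = 0.103), and 1448 genes had an unadjusted p under 0.05, 744 higher and 704 lower with rmMETRNL, where chance alone would give 493. In 2123 genes (21.5%) the 3 values of one group lay wholly beyond the 3 of the other, where chance gives 10%. Of the 5382 genes with a mean of at least 5 FPKM, 95% had a log2 fold change between -0.31 and 0.27, and 14 exceeded 1 in either direction. A second tool chosen after seeing the data, limma voom on the reads recovered from the FPKM values, called 61 genes, 40 higher and 21 lower, and 0 of them reached a 2-fold change. Voom scaled each library by the summed reads of the tested genes, so it also differs from limma on FPKM in scaling. The median log2 fold change over all tested genes was -0.015 in voom and -0.0056 in limma.

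The 10 genes with the smallest p among those higher with rmMETRNL had adjusted p-values of 0.103 to 0.151 in limma, and 7 of the 10 passed voom. Mdm2, the ubiquitin ligase that targets p53 (ENSMUSG00000020184, chromosome 10, 117688875 to 117710758, GRCm38), stood at 185 ± 4.39 FPKM with vehicle and 248 ± 10.6 FPKM with rmMETRNL, a log2 fold change of 0.42 (SE 0.05, adjusted p = 0.138 in limma). Ier3 (ENSMUSG00000003541, chromosome 17, 35821684 to 35822923), a short-lived stress response gene, stood at 1732 ± 32.1 and 2142 ± 28.5 FPKM, a log2 fold change of 0.31 (SE 0.04). Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), a chemokine that attracts neutrophils, stood at 9.003 ± 0.488 and 14.4 ± 1.41 FPKM, a log2 fold change of 0.62 (SE 0.08). The kinase gene Sgk1 had 84.6 ± 3.48 and 110 ± 4.38 FPKM, the atypical chemokine receptor gene Ccrl2 222 ± 3.94 and 281 ± 10.96 FPKM, and Wasl, which encodes an activator of actin branching, 7.19 ± 0.301 and 9.40 ± 0.0969 FPKM. Ankrd37, which shares 22.7% of its exon bases with Lrp2bp on the other strand, is described with its list below. Wfdc21 had 20 to 27 reads per vehicle library and 36 to 44 per rmMETRNL library. The microRNA genes Mir7001 and Mir146 rest on very few reads, 1 per vehicle library against 4 to 6 for Mir7001 and 0 against 2 to 5 for Mir146, so no fold change is given.

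The 10 genes with the smallest p among those lower with rmMETRNL had adjusted p-values of 0.138 to 0.172 in limma, and 5 of the 10 passed voom. Nnmt, the nicotinamide N-methyltransferase gene (ENSMUSG00000032271, chromosome 9, 48591877 to 48605153, GRCm38), stood at 24.4 ± 2.07 FPKM with vehicle and 15.6 ± 0.733 FPKM with rmMETRNL, a log2 fold change of -0.61 (SE 0.07, adjusted p = 0.138 in limma). Mmp3, a secreted matrix metalloproteinase gene, had 22.1 ± 2.24 and 15.3 ± 0.825 FPKM. Gaa, the lysosomal acid glucosidase gene, had 50.9 ± 3.08 and 39.3 ± 0.813 FPKM, and Npy, which encodes neuropeptide Y, 67.9 ± 1.28 and 53.4 ± 2.96 FPKM. Ass1, the argininosuccinate synthase gene, had 55.6 ± 2.74 and 43.1 ± 1.06 FPKM, and is uncertain because 61.5% of its 31-base words occur in other genes. Nol7 had 17.4 ± 0.164 and 14.0 ± 0.551 FPKM, with 16.5% of its exon bases shared with Ranbp9 on the other strand. Snrnp25 (7.33 ± 0.196 and 5.54 ± 0.251 FPKM), Fxyd2 (5.80 ± 0.422 and 4.13 ± 0.113 FPKM) and Rbm43 (2.38 ± 0.0777 and 1.55 ± 0.0136 FPKM) were low in both groups. Mir7086 had 1 to 4 reads per vehicle library and 0 in each rmMETRNL library.

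**Figure D1:**
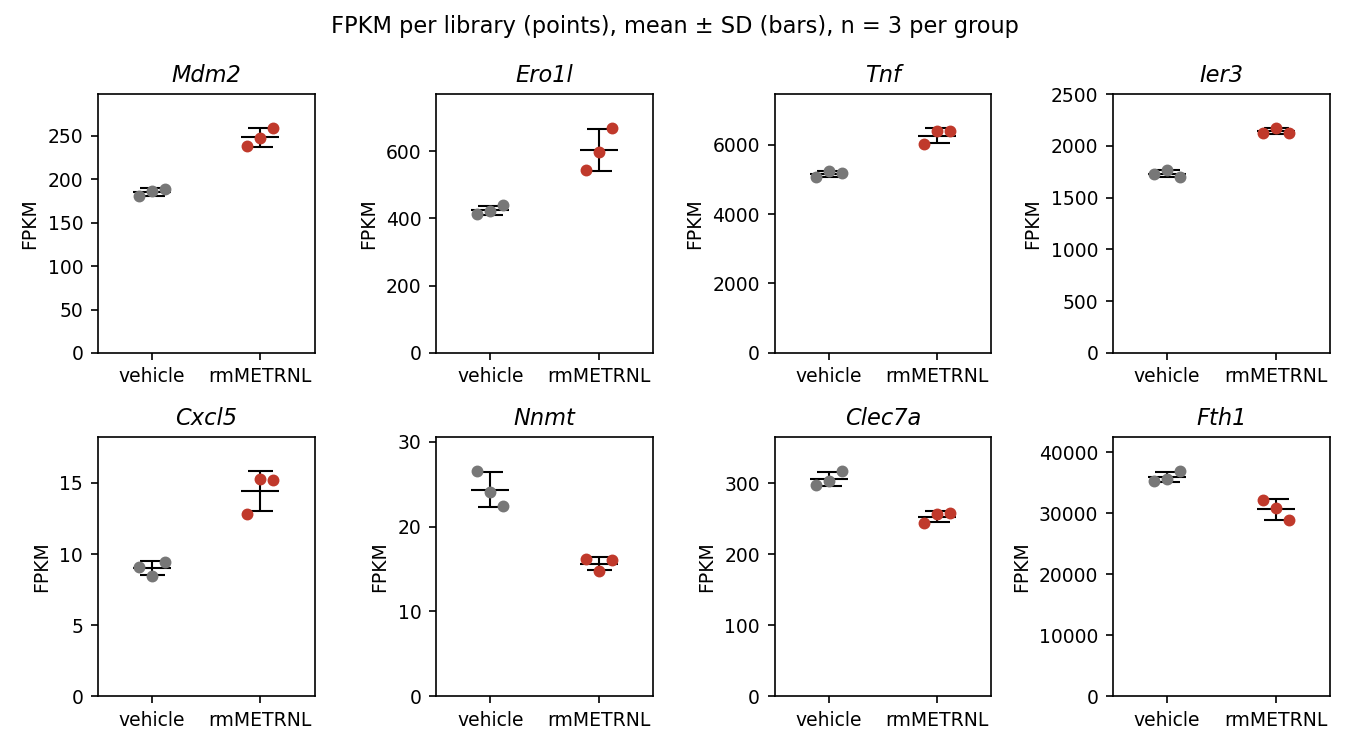
FPKM (vertical axes, starting at 0) of 8 genes in each library, vehicle in grey and rmMETRNL in red, with black bars for the mean ± SD of n = 3. In each panel the 3 rmMETRNL values lie wholly above (Mdm2, Ero1l, Tnf, Ier3, Cxcl5) or below (Nnmt, Clec7a, Fth1) the 3 vehicle values, and in limma 0 of the genes passed an adjusted p of 0.05.

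Hypoxia and HIF-1 targets, genes induced when oxygen is scarce, formed the tested list with the largest median. All 18 tested members had a positive log2 fold change (camera adjusted p = 1.76e-08, and adjusted p = 0.441 with an estimated correlation), with a median of 1.12-fold. In 12 of the 18 the rmMETRNL values lay wholly above the vehicle values. None passed over all genes tested, and 9 passed when adjusted over the list alone. The endoplasmic reticulum oxidoreductase gene Ero1l stood at 424 ± 13.0 FPKM with vehicle and 603 ± 62.8 FPKM with rmMETRNL (log2 fold change 0.50, SE 0.08). Ankrd37 had 65.7 ± 1.52 and 82.4 ± 3.58 FPKM, the lipid droplet gene Hilpda 648 ± 6.25 and 727 ± 23.03 FPKM, and the prolyl hydroxylase gene Egln3 168 ± 2.22 and 189 ± 7.09 FPKM. The list mean was higher than in each vehicle library in 3 of 3 rmMETRNL libraries.

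Glycolysis genes, of which the hypoxia list shares Slc2a1 and Pdk1, rose as a list by a median of 0.05, with 16 of 22 tested members positive (camera adjusted p = 0.0400, and adjusted p = 0.483 with an estimated correlation). The hexokinase genes Hk2 (76.9 ± 2.72 and 89.3 ± 3.42 FPKM) and Hk1 (68.1 ± 4.13 and 77.4 ± 1.86 FPKM), the lactate transporter gene Slc16a3 (181 ± 9.44 and 205 ± 6.14 FPKM) and Pfkfb3 (57.1 ± 1.37 and 65.7 ± 4.87 FPKM) had the smallest p, and 0 members passed when adjusted over the list alone. In 1 of 3 rmMETRNL libraries the list mean lay above the vehicle range, and in 3 of 3 when Gapdh, which varied widely within both groups, was left out, a choice made after seeing the data. This call was lost without vehicle library 2 (adjusted p = 0.0874), vehicle library 3 (0.108), rmMETRNL library 1 (0.0767) or rmMETRNL library 2 (0.0810), with quantile normalization (0.0633) and with a minimum of 5 FPKM (0.103). The medians in these fits were 0.04 to 0.06, close to that with all libraries, and leaving out genes that share sequence moved the median to 0.08.

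Inflammatory cytokine genes rose as a list, with 12 of 17 tested members positive (camera adjusted p = 4.89e-04, and adjusted p = 0.441 with an estimated correlation). Of these, 0 passed over all genes tested and 4 passed when adjusted over the list alone. Tnf (ENSMUSG00000024401, chromosome 17, 35199381 to 35202007, GRCm38), the tumour necrosis factor gene, stood at 5158 ± 91.3 FPKM with vehicle and 6262 ± 223 FPKM with rmMETRNL (log2 fold change 0.28, SE 0.04). Il23a, which encodes a subunit of interleukin-23, had 9.34 ± 1.12 and 12.6 ± 0.496 FPKM, and the colony-stimulating factor genes Csf2 and Csf1 had 27.1 ± 4.96 and 38.9 ± 2.27, and 23.7 ± 0.646 and 27.2 ± 1.251 FPKM. Csf2 shares 12% of its exon bases with an antisense gene. The list median of 0.12 was 0.18 without rmMETRNL library 1, 0.08 without rmMETRNL library 3 (adjusted p = 0.0170 in camera) and 0.20 with a minimum of 5 FPKM.

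NF-kappaB targets and feedback genes rose as a list, with 17 of 23 members positive and 11 wholly above the vehicle range (camera adjusted p = 4.89e-04, and adjusted p = 0.441 with an estimated correlation). Adjusted over the list alone 4 passed, Ier3, Nfkbiz (45.0 ± 1.14 and 59.0 ± 5.29 FPKM), Nfkbia (337 ± 3.53 and 374 ± 2.03 FPKM) and Rel (31.4 ± 1.55 and 37.2 ± 2.42 FPKM), and 0 passed over all genes tested. Ier3 and Nfkbia act as inhibitors or feedback regulators in this pathway. Nfkbiz encodes a nuclear regulator of NF-kappaB target genes, and Rel is one of the pathway's transcription factors. Immediate-early genes rose as a list with 18 of 24 members positive (camera adjusted p = 3.02e-04, and adjusted p = 0.483 with an estimated correlation), and 5 passed when adjusted over the list alone against 0 over all genes tested. The kinase phosphatase genes Dusp6 (30.5 ± 0.232 and 38.4 ± 2.15 FPKM) and Dusp1 (178 ± 6.54 and 209 ± 12.7 FPKM) and the transcription factor genes Jun (60.9 ± 3.32 and 72.5 ± 1.92 FPKM) and Maff (126 ± 2.42 and 142 ± 3.78 FPKM) led the list. Its median of 0.09 was 0.04 without vehicle library 2 and 0.13 without vehicle library 1.

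Unfolded protein and integrated stress response genes rose as a list with 20 of 22 members positive (camera adjusted p = 0.00187, and adjusted p = 0.441 with an estimated correlation). Herpud1, a component of endoplasmic reticulum-associated degradation, stood at 42.8 ± 2.64 and 51.3 ± 0.465 FPKM and was the 1 member that passed when adjusted over the list alone. Chac1 had 19.6 ± 1.77 and 23.5 ± 1.28 FPKM and the chaperone gene Hspa5 234 ± 4.28 and 254 ± 11.4 FPKM, while Xbp1, a transcription factor of the unfolded protein response, had 47.8 ± 0.244 and 43.3 ± 1.87 FPKM. Apoptosis and survival genes rose as a list with 17 of 22 members positive (camera adjusted p = 0.00258, and adjusted p = 0.441 with an estimated correlation). Mdm2 was the 1 member that passed when adjusted over the list alone, followed by Cflar (24.6 ± 0.756 and 30.7 ± 2.94 FPKM), Mcl1 (439 ± 10.03 and 485 ± 4.71 FPKM) and Bcl2l1 (26.4 ± 0.533 and 29.5 ± 1.61 FPKM). Cflar, Mcl1 and Bcl2l1 are known as inhibitors of cell death, and Mdm2 as an inhibitor of p53.

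Ribosomal protein genes fell as a list, with 43 of 46 members negative (camera adjusted p = 1.76e-08, and adjusted p = 0.498 with an estimated correlation), and 0 members passed when adjusted over the list alone. Rpl7 stood at 225 ± 6.86 FPKM with vehicle and 199 ± 9.57 FPKM with rmMETRNL, Rplp2 at 261 ± 28.8 and 210 ± 22.8 FPKM, Rpl8 at 561 ± 24.4 and 488 ± 39.98 FPKM, and Rpl15 at 104 ± 2.71 and 96.0 ± 2.20 FPKM. The list mean lay below the vehicle range in 1 of 3 rmMETRNL libraries, library 3, at -0.27 against the vehicle mean, with rmMETRNL libraries 1 and 2 at -0.06 and -0.08 and vehicle library 1 at -0.08. Without rmMETRNL library 3 the median was -0.08 (adjusted p = 9.58e-05). That library also had the strongest correlation, across genes, of its deviation with gene length, 0.352, where the other 5 lay between -0.215 and -0.0162. A median of 38.1% of the 31-base words of these genes occur in other genes.

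Genes of the TCA cycle and oxidative phosphorylation, the mitochondrial energy pathways, fell as a list with 27 of 34 members negative and 12 wholly below the vehicle range (camera adjusted p = 5.47e-04, and adjusted p = 0.441 with an estimated correlation). Again 0 members passed when adjusted over the list alone. The complex I gene Ndufv1 had 23.1 ± 0.386 FPKM with vehicle and 19.0 ± 1.248 FPKM with rmMETRNL, the isocitrate dehydrogenase genes Idh3b and Idh3g had 23.5 ± 1.31 and 19.5 ± 1.55, and 12.8 ± 0.672 and 11.01 ± 0.514 FPKM, and Dlst had 18.8 ± 0.591 and 17.1 ± 0.261 FPKM. The list median of -0.08 was -0.06 without rmMETRNL library 3. The 12 tested genes encoded in the mitochondrial genome had a median of 0.07 and did not pass (camera adjusted p = 0.442), and mitochondrial reads made up 1.33% to 1.58% of each library.

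**Figure D2:**
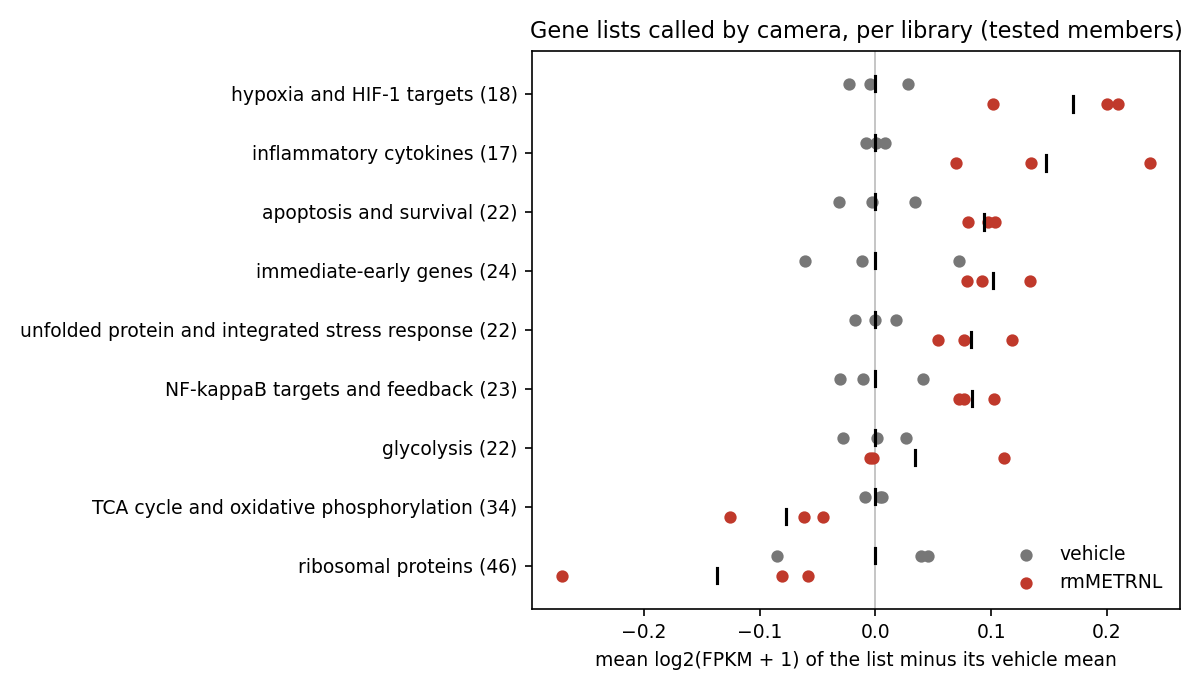
Mean log2(FPKM + 1) over the tested members of each of the 9 lists called by camera, minus its mean over the vehicle libraries (horizontal axis), for each library, vehicle in grey and rmMETRNL in red, with a black bar for the group mean. The 3 rmMETRNL libraries lie wholly beyond the vehicle libraries for 7 lists, and for ribosomal proteins and glycolysis, a list that includes the widely varying Gapdh, 1 rmMETRNL library does.

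Receptors for fungal cell walls did not move together, with 9 of 17 tested members positive (camera adjusted p = 0.997). Adjusted over the list alone 3 members passed. Clec7a (ENSMUSG00000079293, chromosome 6, 129461591 to 129472779, GRCm38), which encodes the beta-glucan receptor Dectin-1, stood at 306 ± 9.87 FPKM with vehicle and 253 ± 7.70 FPKM with rmMETRNL, and Cd14 at 2647 ± 62.0 and 2298 ± 53.4 FPKM. Tlr2 went the other way, at 76.4 ± 1.40 and 88.3 ± 2.66 FPKM, and Mrc1, the mannose receptor gene, had 14.0 ± 0.929 and 16.5 ± 1.31 FPKM. Clec7a and Cd14 passed voom and did not pass limma over all genes tested. The list of Dectin and CARD9 signalling genes also holds Toll-like receptor signalling genes such as Myd88. It had a median of 0.01 (camera adjusted p = 0.508), with 16 of 28 tested members positive. Myd88 (9.65 ± 0.217 and 11.5 ± 0.233 FPKM), which overlaps Acaa1a over 11.3% of its exon bases, led the list. Syk had 86.8 ± 5.17 and 87.3 ± 5.36 FPKM, and Card9 12.2 ± 1.80 and 10.5 ± 1.40 FPKM.

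Chemokine genes had 10 of 16 tested members positive and did not pass (camera adjusted p = 0.0689, and 0.0260 on the voom values, where they did), with the list mean above the vehicle range in 3 of 3 rmMETRNL libraries, and Cxcl5 and Cxcl1 (749 ± 18.6 and 912 ± 34.6 FPKM) passed when adjusted over the list alone. Cxcl2 had 5085 ± 257 and 6110 ± 523 FPKM and Ccl7 25.6 ± 1.32 and 30.2 ± 3.43 FPKM. Alternative activation and anti-inflammatory genes had 10 of 20 members positive (camera adjusted p = 0.101), and the interleukin-10 gene Il10 (20.2 ± 1.09 and 25.7 ± 1.85 FPKM) and the arginase gene Arg1 (429 ± 27.0 and 514 ± 16.1 FPKM) passed when adjusted over the list alone. In the list of NRF2 and antioxidant genes, 4 members passed that way and all 4 were lower with rmMETRNL, the glutathione synthesis genes Gclc (27.9 ± 0.586 and 23.2 ± 1.18 FPKM) and Gclm (33.9 ± 0.996 and 29.6 ± 0.458 FPKM), the metallothionein gene Mt1 (443 ± 21.3 and 359 ± 28.5 FPKM) and Fth1, while the list of 25 did not pass (camera adjusted p = 0.151). Heat shock response genes split, with Hspa8 (217 ± 8.42 and 184 ± 5.68 FPKM), Hspa1b (10.8 ± 0.622 and 6.89 ± 1.39 FPKM) and Hsp90ab1 (446 ± 1.84 and 406 ± 14.8 FPKM) lower and Hsp90aa1 (198 ± 6.00 and 222 ± 10.8 FPKM) higher when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.112, and 0.0410 on the voom values, where it did). Over 50% of the 31-base words of Hspa8, Hspa1b and Hsp90aa1 occur in other genes.

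Single members of other lists passed when adjusted over the list alone, where the list did not pass camera. Plau (36.1 ± 1.93 and 43.4 ± 0.855 FPKM), which encodes a plasminogen activator, was higher in the list of matrix remodelling and wound genes (list adjusted p = 0.850). The lipoprotein lipase gene Lpl (13.1 ± 0.601 and 16.7 ± 0.280 FPKM) was higher among PPAR and fatty acid oxidation targets (0.997), the prostaglandin E synthase gene Ptges (166 ± 1.16 and 191 ± 7.67 FPKM) among eicosanoid genes (0.123), and Fabp7 (5.97 ± 0.189 and 7.94 ± 0.771 FPKM) among resident peritoneal macrophage markers (0.993). The necroptosis effector gene Mlkl (13.5 ± 1.06 and 10.5 ± 0.236 FPKM) was lower among inflammasome and pyroptosis genes (0.997), and Map1lc3a (18.9 ± 0.750 and 15.3 ± 0.553 FPKM) among lysosome and autophagy genes (0.993).

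In the macrophage identity list (median 0.05, camera adjusted p = 0.292) Cd14 passed when adjusted over the list alone. Interferon-stimulated genes had 10 of 17 members positive (camera adjusted p = 0.997), with a median of 0.04, a mean of -0.01 and a negative test direction, and 0 passed when adjusted over the list alone. Such signs also differed for the PPAR (median 0.01, mean -0.0041), matrix (median 0.01, mean -0.0081), resident peritoneal (median 0.0076, mean -0.02) and inflammasome lists (mean -8.56e-04, positive test direction). The camera adjusted p was 0.123 for oxidative and nitrosative killing, 0.442 for cholesterol biosynthesis and for complement, 0.508 for MHC class II and co-stimulation, 0.557 for LXR targets, for MHC class I and for phagocytosis and opsonin receptors, and 0.874 for the cell cycle. Their medians were -0.05, 0.0093, 0.04, 0.02, -0.04, -0.0046, 0.01 and 0.02 in that order, and 0 of their members passed when adjusted over the list alone.

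Metrnl itself stood at 145 ± 6.41 FPKM with vehicle and 149 ± 4.87 FPKM with rmMETRNL (log2 fold change 0.04, SE 0.05), a difference within the spread. Kit, a receptor tyrosine kinase gene in the list of proposed partners, was below the level tested, at 0.454 ± 0.0618 and 0.444 ± 0.0944 FPKM from 47 to 77 reads per library, and 3 members of that list were tested, too few for camera.

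Markers of other cell types were low next to the most abundant macrophage genes, such as Lyz2. Several stood above low macrophage identity genes such as Mertk (2.74 ± 0.00384 and 2.18 ± 0.462 FPKM). Among neutrophil markers S100a8 had 83.7 ± 4.59 and 86.1 ± 0.564 FPKM and Mmp8 71.9 ± 1.56 and 77.0 ± 4.56 FPKM, and S100a9 (24.4 ± 0.781 and 34.8 ± 3.56 FPKM) passed when adjusted over the list alone (list camera adjusted p = 0.0689). The mean of the 7 tested neutrophil markers lay above the vehicle range in 3 of 3 rmMETRNL libraries, as did that of the cytokine genes. B cell markers Ighm and Igkc had 13.8 ± 2.37 and 13.6 ± 1.06, and 9.50 ± 1.73 and 9.64 ± 1.39 FPKM (list adjusted p = 0.221), and the fibroblast markers Dcn and Acta2 had 4.27 ± 0.259 and 4.30 ± 0.115, and 3.83 ± 0.458 and 3.34 ± 0.427 FPKM (list adjusted p = 0.557). The other marker lists had too few tested members for camera. Of T and NK cell markers Il7r had 68.9 ± 3.43 and 74.7 ± 3.26 FPKM and Gzmb 3.55 ± 0.413 and 3.44 ± 0.478 FPKM. Trbc2, with 1.04 ± 0.0691 and 1.72 ± 0.202 FPKM, passed when adjusted over the list alone, which had 4 tested members. It rests on few reads, 9 to 21 per library. Dendritic cell markers Ccr7 and Fscn1 had 28.3 ± 1.39 and 27.6 ± 1.42, and 12.03 ± 0.399 and 12.7 ± 0.914 FPKM. Mast cell markers Tpsb2 and Hdc had 6.96 ± 1.74 and 6.75 ± 0.0758, and 6.40 ± 0.244 and 6.83 ± 0.506 FPKM. The endothelial marker Cdh5 had 1.30 ± 0.248 and 1.24 ± 0.388 FPKM and the epithelial marker Cdh1 0.634 ± 0.124 and 0.816 ± 0.226 FPKM. Pf4, a platelet gene that macrophages also express, had 60.8 ± 7.26 and 77.4 ± 3.89 FPKM and passed when adjusted over its list alone, while Ppbp had 1.17 ± 0.0651 and 1.21 ± 0.499 FPKM. Of 15 retina markers, checked because the labels' extraction text speaks of retinas, 1 was above 1 FPKM, the widely expressed Glul (22.9 ± 0.999 and 20.3 ± 1.08 FPKM), which passed as the sole tested member of its list. Pde6b had 0.351 ± 0.0687 and 0.522 ± 0.1705 FPKM.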

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

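Tests named here as chosen after seeing the data are voom, robust variances, the restrictions to protein-coding genes or genes with little shared sequence, and the trend removals. The limma count of 0 genes was also 0 with both other pseudocounts, a minimum of 5 FPKM, median-of-ratios scaling, quantile normalization, no variance trend, the length trend removed, thresholds of 0.01 and 0.1, and each library left out (0 to 0). It was 5 with no filter (Gm24384, Mir7227, Gm25220, Gm23341 and Mir3470b, all with 0 reads in the vehicle libraries and at most 2 in any rmMETRNL library), and 1, Mir7001, with TPM scaling, with array weights, with robust variances and with the GC trend removed. It was 6 among protein-coding genes (Nnmt, Wfdc21, Mdm2, Cxcl5, Ero1l and Sgk1), where 8532 genes were tested, 6 without genes that share sequence (Mir7001, Mdm2, Mir146, Ier3, Nnmt and Wfdc21), where 8093 were, and 61 with voom. The number at an unadjusted p under 0.05 lay between 1028 (without rmMETRNL library 3) and 1394 with a library left out. Of the named genes, 0 changed direction.

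Of the camera list count, 9, the settings with the preset correlation gave 8 to 11, leaving out a library gave 8 to 11, and an estimated correlation and fry gave 0 (lowest adjusted p = 0.441 and 0.119). With fry's test of movement in either direction 25 lists passed. Without Gapdh, also chosen after seeing the data, 9 lists passed, glycolysis among them (adjusted p = 0.0253). Of 198 refits of the 9 called lists with the preset correlation, 191 remained past the threshold and the other 7 were all of the glycolysis list, and the cause was not tested. Of the lists not called, chemokines passed with TPM scaling, voom, the length trend removed and without vehicle library 2, vehicle library 3 or rmMETRNL library 1, heat shock genes with voom and without vehicle library 2, neutrophil markers with the length trend removed and without vehicle library 2 or rmMETRNL library 1, mitochondrially encoded genes without vehicle library 3, and alternative activation genes with no filter. No list changed direction while past the threshold, and uncalled lists changed direction 56 times. Members past the threshold numbered 0 over all genes and 50 adjusted over the list alone, by the smaller number of tests. With the replicate number as a block, 0 genes and 8 lists were called, glycolysis being lost (adjusted p = 0.0781). The numbers share nothing visible, since deviations of libraries with the same number correlated at -0.0212, 0.0074 and -0.0454 across genes, and 0 of 6 libraries were closest to their own number. The tests planned for files of whole counts were not run, as the table holds FPKM. Depth limits low genes, as a gene of 1 kb with 10 reads has 0.549 to 0.748 FPKM.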

Other observations

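The tests below of the length trend, of a single library and of the spread of glycolysis genes were chosen after their results were seen, as were voom and the SE between libraries. Voom called genes that are not yet named above, and the ones given here were picked after their values were seen. F3, which encodes tissue factor, stood at 606 ± 1.70 FPKM with vehicle and 760 ± 53.2 FPKM with rmMETRNL (voom adjusted p = 0.0168), F13a1, a clotting factor subunit gene, at 25.8 ± 1.19 and 32.1 ± 1.58 FPKM (0.0349), and Mcfd2, a cargo receptor for clotting factors, at 44.8 ± 0.853 and 56.3 ± 3.99 FPKM (0.0409). The lysyl oxidase gene Lox stood at 5.78 ± 0.520 and 8.17 ± 0.403 FPKM (0.0228). Lower with rmMETRNL were the integrin gene Itgb7 (105 ± 5.70 and 82.7 ± 4.64 FPKM, 0.0203), the metalloproteinase gene Adam8 (402 ± 22.3 and 335 ± 5.87 FPKM, 0.0294) and the actin gene Actb (3092 ± 180 and 2589 ± 58.6 FPKM, 0.0230), whose sequence is shared with other genes over 35.1% of its words. None of these passed limma on log2(FPKM + 1), where their adjusted p ranged from 0.169 to 0.189.

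The 6 libraries make 10 splits into 3 and 3, so no share under 0.1 can be reached and chance cannot be told apart from the pretreatment by them. The real split gave 1448 genes at an unadjusted p under 0.05, against at most 509 in another split, so that 1 of the 10 splits gave as many. It gave 61 genes with voom, against at most 5, and 9 lists with camera, against at most 6, again with 1 split as high. By limma at an adjusted p of 0.05 the real split called 0 genes (at most 2 in another), and as each of the 10 splits must give at least 0, that count says nothing about chance.

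Hypoxia and HIF-1 target genes were higher with rmMETRNL by a median log2 fold change of 0.17. Removing each library's GC trend gave a median of 0.18 (SE over genes and SE between libraries both 0.04), removing the length trend gave 0.19 (both 0.04), and leaving out rmMETRNL library 3 gave 0.15 (SE over genes 0.04, between libraries 0.05), which argues against each of these as the whole cause. A response to the pretreatment is a hypothesis that these values leave open. A difference in oxygen or cell density between the cultures of the groups could give the same pattern and was not tested.

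Ribosomal protein genes were lower with rmMETRNL by a median of -0.15, but these genes move together (estimated correlation 0.574), so an SE over genes is too small, and that between libraries was 0.08. After removal of the length trend the median was -0.13 (SE between libraries 0.06), narrowly beyond 2 SE, which argues weakly against gene length as the whole cause. It was -0.0802 (SE between libraries 0.04) without rmMETRNL library 3, so that library as the whole cause cannot be told apart from a difference between the groups. Nor can reads shared with other genes, since the median was -0.13 (SE over genes 0.02, between libraries 0.07) when the reads of 45 of the genes were summed with those of all genes that share words with them, and -0.16 before.

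Gapdh, often used as a reference gene, ranged from 7.48 to 49.9 FPKM (479 to 3115 reads), at 7.65, 30.1 and 41.4 FPKM in vehicle libraries 1, 2 and 3 and 7.77, 7.48 and 49.9 FPKM in rmMETRNL libraries 1, 2 and 3, far below Pgk1 (917 ± 16.5 and 919 ± 17.9 FPKM). The SD of its log2 values within groups was 1.35, while the other 21 tested glycolysis genes had a median SD of 0.0622 (highest 0.143), which argues against a change in glycolysis gene expression. Reads shared with its many pseudogenes are a candidate explanation. Genes with over 50% of their words shared had an SD 1.74 times that of genes with under 5% shared at the same read number, but 30.7% of the words of Gapdh are shared in the transcript used, so this source cannot be told apart from others.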
